A study of Homo sapiens with 6 samples.

How the data were processed

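Total RNA of PC-3 cells was extracted with TRIzol and treated with DNase I, and stranded total RNA libraries were made with the SMARTer kit of Takara and sequenced on an Illumina NovaSeq as paired reads, per the labels. The labels name 3 libraries Ctrl and 3 MTA1, and the data columns carry the prefixes NC and shMTA1. The shMTA1 columns were matched to the MTA1 samples by name and the NC columns to the Ctrl samples by elimination, with replicate numbers kept. The labels name lentivirus, transfection and the screening of stable clones.

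The authors counted reads per gene and deposited whole-number counts without normalization, for 30651 genes with at least 1 read in some library. The deposited FPKM values, for 29969 of these genes, were scaled by the authors for gene length and sequencing depth and rounded to 2 decimals. The ratio of counts to FPKM between libraries was checked over 3526 genes and was constant from gene to gene. The 682 genes found only among the counts had at most 41 reads in total. The aligner, the counting tool, its strand setting, the genome build and the annotation are not given in the sources used here, so genes that overlap another on the opposite strand are uncertain. The submitters' processing notes name DESeq2 without a role or a version. Genes were taken by the identifiers and symbols of the count table, and 1 list gene was matched through an older symbol.

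The count depth ran from 29909172 to 33849262 per library. Between replicates of a group the biological coefficient of variation was 4.45% over the tested genes. Squared differences between replicates were 3.27 to 9.21 times counting noise, against 89.6 to 97.7 times between libraries of different groups. On a multidimensional scaling of 500 genes, the first dimension held 66.1% of the variance and parted the groups. On simulated data with 15423 genes and the same group sizes, the test recovered 46% of 50 genes changed 1.2-fold, 66% of those changed 1.5-fold, 88% at 2-fold and 98% at 4-fold, with 6 false calls among 155. Of 20 simulated lists of 25 genes, the list test called 1, the one that had been shifted by 0.4 on the log2 scale. The simulated genes varied independently, and few were changed, against 58.1% that passed in the data. The simulations therefore do not give the recovery in this comparison. They also do not give the false calls of the list test among correlated genes.

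Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with default settings, which left 15423 genes and removed 15228, with over 99.9% of the counts retained. TMM normalization and the quasi-likelihood F test with group as the only term were used, 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors of log2 fold changes come from the same fit, and CPM values use TMM-scaled library sizes. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, 2-sided, each against all other tested genes, and adjusted over the 27 lists with 3 or more measured members.

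Before the data were examined, the 27 lists, the tests, the alternatives and the rule for naming genes were fixed. The lists covered the NuRD complex, mesenchymal and epithelial genes, matrix proteases, hypoxia, interferon-stimulated genes, MHC class I presentation, NF-kB and cytokines, mitosis, DNA replication, histones, p53 targets, luminal prostate genes, neuroendocrine genes, splicing regulators, the spliceosome core, the unfolded protein response, heat shock, cholesterol synthesis, immediate early genes, ribosomal proteins, ribosome biogenesis, mitochondrially encoded genes, structural RNAs, and markers of fibroblasts, leukocytes and HEK293 cells. The rule named MTA1. It also named the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean of 2 CPM or more, no overlap between the groups and a symbol that was not clone-based, antisense, a pseudogene, an open reading frame or a small or long non-coding RNA name. This left out 1 gene at the low end by its name. From each list the rule took up to 3 members with the smallest p in the direction most called members took and up to 1 in the other, and it took the 3 most abundant genes past the threshold in each direction. Not every gene taken by the rule is given in the text. Further named genes were chosen after their values were seen and are marked so.

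The alternatives fixed in advance were DESeq2 1.42.0 size factors, upper-quartile and library-size scaling in edgeR, no filter, a filter of 1 CPM in 3 libraries, the DESeq2 Wald test (with its statistics in a preranked camera test for lists), limma-voom, limma on log2(FPKM + 0.1) and log2(FPKM + 1), the replicate number as a block, each library left out in turn, the 20 most abundant and the mitochondrial genes left out, camera with an estimated correlation, and fry. After the data were seen, 8 more lists were written and 6 alternatives added: protein-coding genes only, a correction for GC content and transcript length with mgcv 1.9.3, a minimum fold of 1.2 in the edgeR test (glmTreat), the NuRD list without MTA1, the added lists without members of a fixed list or genes taken by the naming rule, and the other splits of the libraries with an estimated correlation. GENCODE 29 gave GC content, transcript and coding length, and gene order, and may differ from the annotation of the deposited tables.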

Results

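RNA from PC-3 cells, a human cell line from a bone metastasis of prostate cancer, was sequenced in 6 libraries. The control group (Ctrl) and the group named after MTA1 held 3 libraries each. MTA1 is a subunit of the NuRD chromatin-remodelling and deacetylase complex. Per the file headers, the columns of the MTA1 group carry the prefix sh, the usual prefix for a short hairpin RNA. The labels name lentivirus and stable clones but not how many hairpins or clones stood behind the libraries, and they do not say that the libraries came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical. The title of the series names oncogenic gene expression and splice variants, so the comparison asks which genes differ in expression between the MTA1 group and the control. The deposited values are per gene, and splicing was not analysed here. The libraries held 31726013, 33352582 and 33849262 counts in Ctrl replicates 1, 2 and 3 and 29909172, 30938820 and 30266580 in the MTA1 replicates. Of 30651 genes listed, 15423 had enough counts to be tested. Levels are given in CPM, counts scaled to a common library size with TMM, as mean ± SD over n = 3 libraries, and log2 fold changes of the MTA1 group over Ctrl are given ± SE.

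MTA1 itself (ENSG00000182979.18, chromosome 14 in the files) was lower in each library of the MTA1 group than in any Ctrl library. It had 1185, 1331 and 1352 counts in Ctrl replicates 1, 2 and 3, and 528, 572 and 519 in the MTA1 replicates. The level fell from 40.0 ± 1.47 to 17.4 ± 0.660 CPM, which left 43.4% of the control level (log2 fold change -1.21 ± 0.054, edgeR adjusted p = 4.3e-13). In the deposited FPKM values it fell from 4.96 ± 0.208 to 2.26 ± 0.0764. The direction in all 3 libraries is that of a knockdown, and a gene called higher or lower is so in the libraries with less MTA1.

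**Figure D1:**
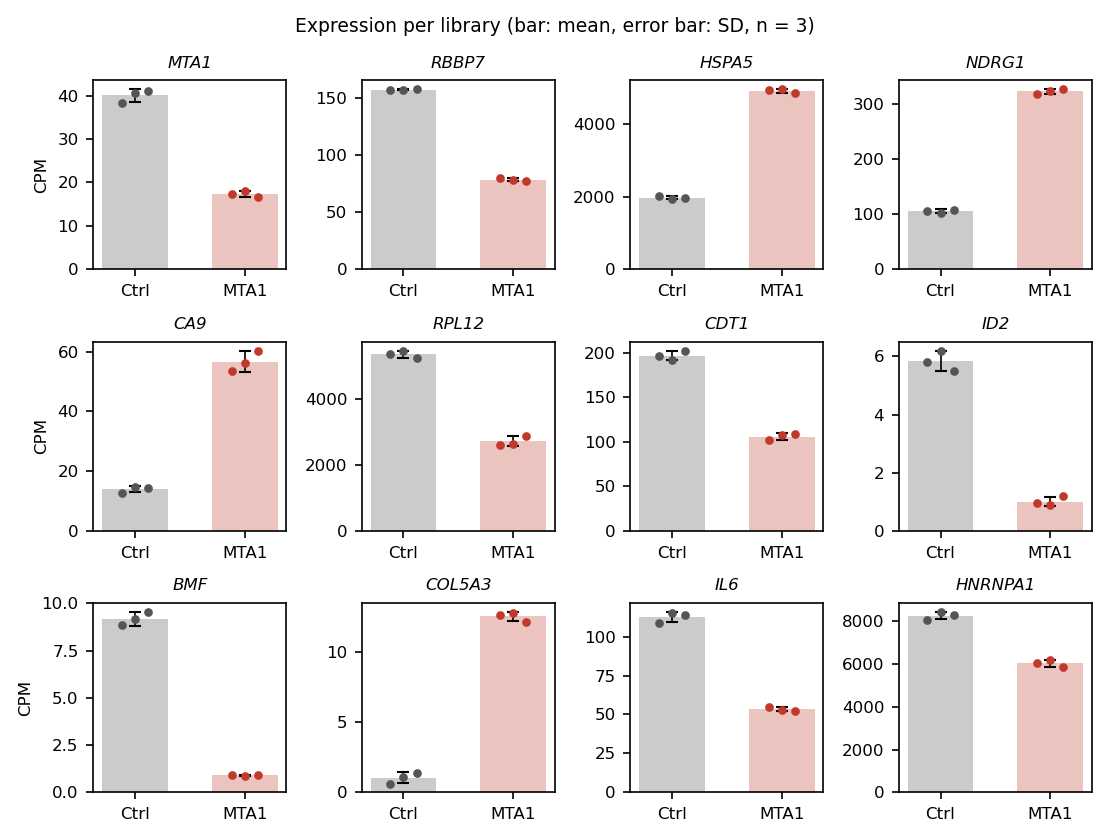
Expression in CPM (y axis, from 0, own scale in each panel) of 12 genes in the 6 libraries. Bars are means, error bars SDs and points single libraries, n = 3 per group; for each of the 12 genes the points of the groups do not overlap, as for MTA1 at 38.3 to 41.1 CPM in Ctrl and 16.7 to 18.0 CPM in the MTA1 group.

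Most of the tested genes differed. At an adjusted p under 0.05 in edgeR's quasi-likelihood test, 8954 genes (58.1%) passed, 4550 higher and 4404 lower in the MTA1 group. Genes described as rising or falling passed this threshold. Most changes were small. The median absolute log2 fold change of these genes was 0.44, and 2050 of them differed by less than 1.2-fold. A change of at least 2-fold was seen in 954 genes, 440 higher and 514 lower. When the test asked for a minimum fold of 1.2, a choice made after the data were seen, 4650 genes passed. Without overlap between the libraries of the groups were 9676 genes (62.7%), against 10% for chance. Of 1862 long non-coding RNAs tested, 808 passed, 341 higher and 467 lower. The count of 2-fold changes fell to 600 when genes under 1 CPM were removed, and it fell further on the FPKM scale.

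The largest rises were of several kinds. COL5A3, a fibrillar collagen chain, rose from 1.04 ± 0.395 to 12.5 ± 0.316 CPM (log2 fold change 3.58 ± 0.14). LCN2, an iron-siderophore carrier of epithelia and neutrophils, rose from 2.59 ± 0.572 to 30.9 ± 3.03 CPM (3.57 ± 0.11). IGFBP3, which binds insulin-like growth factors, rose from 33.2 ± 0.488 to 152 ± 9.12 CPM (2.20 ± 0.049), and DPT, a matrix protein, from 13.8 ± 0.777 to 87.8 ± 4.25 CPM (2.67 ± 0.057). The interleukin-7 receptor gene IL7R (2.82 ± 0.092), the activin subunit INHBE (2.79 ± 0.12), ANKRD22 (3.36 ± 0.21), the surface peptidase DPP4 (2.22 ± 0.14) and the pentraxin PTX3 (2.19 ± 0.088) rose as well. PRSS3, a trypsinogen with near-identical paralogs whose reads could be split, rose by 2.43 ± 0.17 on the log2 scale. The adjusted p of these 10 genes was at most 1.6e-10.

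The largest falls were of a mixed kind. BMF, a pro-apoptotic BCL2-family member, fell from 9.18 ± 0.355 to 0.902 ± 0.0440 CPM (log2 fold change -3.34 ± 0.13). SLC12A3, a sodium-chloride cotransporter, fell from 11.02 ± 0.448 to 0.922 ± 0.0490 CPM (-3.57 ± 0.12). CPS1, the mitochondrial carbamoyl phosphate synthetase of the urea cycle, fell from 48.8 ± 1.72 to 7.97 ± 0.0865 CPM (-2.61 ± 0.058), and ID2, an inhibitor of helix-loop-helix transcription factors, from 5.83 ± 0.350 to 1.01 ± 0.162 CPM (-2.53 ± 0.15). TRIM31 (-3.58 ± 0.203), a ubiquitin ligase, IGFN1 (-2.98 ± 0.17), the mucin MUC16 (-2.87 ± 0.14), the receptor VIPR2 (-2.81 ± 0.195), the alkaline phosphatase ALPI (-2.73 ± 0.19) and KRT14 (-2.63 ± 0.27) completed the 10 lowest. ALPI and KRT14 have close paralogs, so their counts are uncertain. The adjusted p of these 10 genes was at most 4.9e-08. Among the most abundant genes, FTH1, the ferritin heavy chain, fell from 8859 ± 70.6 to 4764 ± 106 CPM (-0.89 ± 0.042), the actin-binding TMSB10 from 12083 ± 303 to 9207 ± 202 CPM (-0.39 ± 0.043) and the splicing factor HNRNPA1 from 8239 ± 173 to 6018 ± 162 CPM (-0.45 ± 0.043). These 3 genes have processed pseudogenes that can share reads.

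**Figure D2:**
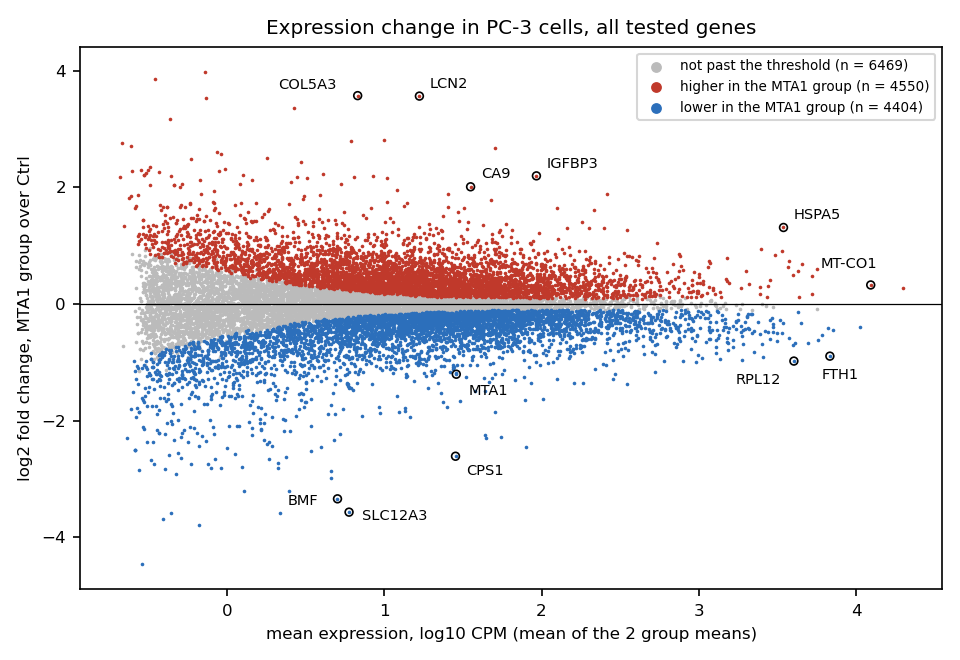
Log2 fold change of the MTA1 group over Ctrl (y axis) against mean CPM on a log10 scale (x axis) for the 15423 tested genes. Red points are the 4550 genes that rose, blue points the 4404 that fell and grey points the 6469 that did not pass; named genes are circled.

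Genes induced by low oxygen rose together. The count of genes that passed was the same when adjusted over the list alone as over all genes in each of the 27 lists fixed before the data were examined, except in the 3 named with both counts. Of 23 measured members of the hypoxia and angiogenesis list, 21 rose and none fell, with a median log2 fold change of 0.66 (camera adjusted p = 1.1e-08, and 0.037 with an estimated correlation). CA9, a carbonic anhydrase of the cell surface, rose from 14.1 ± 1.09 to 56.7 ± 3.52 CPM (2.01 ± 0.063). NDRG1, a stress-induced gene, rose from 106 ± 3.36 to 323 ± 4.38 CPM (1.61 ± 0.040), and the glucose transporter SLC2A1 from 31.9 ± 1.58 to 75.1 ± 2.35 CPM (1.23 ± 0.050). VEGFA, the angiogenic growth factor (0.89 ± 0.046), and HIF1A, whose protein is controlled by oxygen (0.32 ± 0.054), rose too. The members that did not pass were EPAS1 (-0.10), which passed as lower without MTA1 replicate 3 (adjusted p = 0.037) and after a correction for GC content and length (0.0023), and EGLN1 (-0.03). VEGFA, HIF1A, EPAS1 and EGLN1 were chosen after their values were seen.

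Chaperones and stress genes of the endoplasmic reticulum rose too. In the list for the unfolded protein response and amino acid stress, 20 of 27 members rose and 4 fell over all genes, and 21 rose and 5 fell when adjusted over the list alone. Its median was 0.55 (camera adjusted p = 3.5e-05, and 0.049 with an estimated correlation). HSPA5, the main chaperone of this compartment, rose from 1983 ± 39.2 to 4926 ± 48.5 CPM (1.31 ± 0.041). HYOU1, another of its chaperones, rose from 60.2 ± 2.45 to 189 ± 9.10 CPM (1.65 ± 0.047), and the transcription factor DDIT3 from 57.8 ± 2.77 to 135 ± 3.05 CPM (1.23 ± 0.045). PHGDH, which opens serine synthesis, fell (-0.37 ± 0.048), as did the messages of the transcription factors ATF4 (-0.19 ± 0.039), ATF3 (-0.19) and CEBPB (-0.25), these 3 chosen after their values were seen. Of 18 heat shock genes, 14 rose and 1 fell, with a median of 0.21 (camera adjusted p = 0.0099). That call was lost with an estimated correlation (adjusted p = 0.16). HSP90AA1 (0.94 ± 0.050), HSP90AB1 (0.83 ± 0.041) and HSPH1 (0.68 ± 0.039) rose and DNAJA1 (-0.17 ± 0.040) fell, while CRYAB (-0.11), CHORDC1 (-0.08) and HSPA6 (-0.14), chosen after their values were seen, did not pass. HSPA1A and HSPA1B, near-identical copies in this list, cannot be told apart reliably by their reads.

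Cytosolic ribosomal protein genes fell as a group. Of 50 measured, 49 fell and none rose, with a median log2 fold change of -0.44 (camera adjusted p = 2.0e-13, and 0.037 with an estimated correlation). RPL12 fell from 5337 ± 118 to 2707 ± 150.4 CPM (-0.98 ± 0.046), RPL32 from 2882 ± 17.04 to 1626 ± 45.0 CPM (-0.83 ± 0.040) and RPL13 from 1877 ± 20.5 to 1186 ± 9.33 CPM (-0.66 ± 0.039). The exception was RPL10 at 0.05 ± 0.040, which passed as higher when libraries were scaled by their size only and on both FPKM scales (0.12 in each). Coding genes with ribosomal protein symbols took 13.7% to 13.8% of the counts in Ctrl and 10.1% to 10.4% in the MTA1 group. Other short, abundant messages were lower as well. Random lists of genes matched to the ribosomal protein genes on coding length and expression had a median of -0.20, with 95% of them between -0.30 and -0.08. Processed pseudogenes of ribosomal protein genes can share reads with them. Genes for ribosome assembly formed a list of their own. Of 25, 14 rose and 5 fell (15 and 5 when adjusted over the list alone), with UTP20 at 0.64 ± 0.047 and POLR1A at 0.64 ± 0.058 up and RRS1 at -0.39 ± 0.041 down. FBL (-0.27), NHP2 (-0.32) and GAR1 (-0.26) fell as well, chosen after their values were seen. The list did not pass (camera adjusted p = 0.081), though it did with no filter (adjusted p = 0.019), DESeq2 (0.039), limma-voom (0.039) and log2(FPKM + 1) (0.028).

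Transcripts of the mitochondrial genome were higher. They took 5.31% to 5.81% of the counts in Ctrl and 7.10% to 7.77% in the MTA1 group. Long non-coding RNAs took 1.68% to 1.72% of the counts in Ctrl and 1.52% to 1.56% in the MTA1 group. Of the 15 genes, 12 rose and none fell, with a median log2 fold change of 0.40 (camera adjusted p = 0.0073). The call was lost with an estimated correlation (adjusted p = 0.54). MT-CO3, a cytochrome oxidase subunit, rose from 4373 ± 118 to 6105 ± 311 CPM (0.48 ± 0.046). The complex I subunits MT-ND1 (0.59 ± 0.063), MT-ND2 (0.64 ± 0.062) and MT-ND4 (0.74 ± 0.077) rose too, as did MT-CO1 (0.33 ± 0.045) and the ribosomal RNA MT-RNR2 (0.28 ± 0.045), the most abundant of the genes that rose. The genes that did not pass, chosen after their values were seen, were MT-CO2 (-0.08), MT-ND3 (-0.06) and MT-ND6 (0.07). Nuclear copies of mitochondrial genes can share reads with them.

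DNA replication genes fell, and mitotic genes went both ways. Of 27 replication genes, 20 fell and 1 rose, with a median of -0.34 (camera adjusted p = 1.0e-05, and 0.049 with an estimated correlation). The origin-licensing factor CDT1 fell from 197 ± 5.24 to 106 ± 3.83 CPM (-0.89 ± 0.042) and the transcription factor E2F1 from 187 ± 7.33 to 110.1 ± 2.22 CPM (-0.77 ± 0.042), whereas UHRF1, which reads hemimethylated DNA, rose (0.29 ± 0.049). Of 25 mitotic genes, 10 rose and 10 fell (camera adjusted p = 0.97), among them HMMR (0.79 ± 0.052), CENPF (0.34 ± 0.041) and BUB1 (0.37 ± 0.053) upward and BIRC5 (-0.38 ± 0.038) downward. Of 22 replication-dependent histone genes, 9 rose, such as H2BC21 (1.09 ± 0.080), and H2BC11 (-0.49 ± 0.14) fell (camera adjusted p = 0.16, and 0.031 after a correction for GC content and length). The call of H2BC11 ended with log2(FPKM + 0.1) (adjusted p = 0.059) and log2(FPKM + 1) (0.057), and histone genes are near-identical, so their counts are uncertain. Targets of p53 and growth arrest genes were split 8 higher to 7 lower of 24 (camera adjusted p = 0.88), with SESN2 (0.86 ± 0.054) and FAS (0.86 ± 0.084) up and GADD45B (-0.75 ± 0.056) down. Their median was -0.004 and their mean 0.07, and the median turned positive without MTA1 replicate 1 (0.01) or 3 (0.02), with no filter (0.003), on both FPKM scales (0.06 and 0.05) and when libraries were scaled by size only (0.06). The arrest gene CDKN1A, chosen after its value was seen, stood at 0.04 ± 0.061.

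Several partners of MTA1 in the NuRD complex were lower. Of 14 members, 9 fell and 1 rose, with a median log2 fold change of -0.26 (camera adjusted p = 0.012). The list holds MTA1 itself, and without it the adjusted p was 0.033. The call was lost with an estimated correlation (adjusted p = 0.16, and 0.21 without MTA1). RBBP7, a histone-binding subunit, fell from 157 ± 0.516 to 78.3 ± 1.11 CPM (-1.0 ± 0.039) and the deacetylase HDAC1 from 214 ± 11.96 to 153 ± 5.87 CPM (-0.49 ± 0.045). The paralog MTA2 fell (-0.29 ± 0.044), while HDAC2 (-0.02), MTA3 (-0.03), CHD4 (-0.08) and GATAD2B (0.10, passing as higher at 0.16 with scaling by library size only) did not pass, these 5 chosen after their values were seen. The remodeller CHD3 rose slightly (0.11 ± 0.039), a call that ended without Ctrl replicate 1 (adjusted p = 0.084), Ctrl replicate 2 (0.16) or MTA1 replicate 2 (0.069), and after a correction for GC content and length (0.89).

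Genes of the mesenchymal state moved in both directions. Of 25, 13 rose and 10 fell (camera adjusted p = 0.29). The matrix protein TNC rose from 18.6 ± 0.749 to 49.1 ± 1.73 CPM (1.40 ± 0.054), the fibronectin receptor subunit ITGA5 from 80.4 ± 2.60 to 174 ± 9.45 CPM (1.11 ± 0.046) and the collagen cross-linking enzyme LOX from 3.81 ± 0.946 to 16.9 ± 0.609 CPM (2.16 ± 0.11), whereas CCN2, a matricellular protein, fell from 27.7 ± 1.29 to 10.2 ± 1.03 CPM (-1.45 ± 0.069). The transcription factor SNAI2 (-2.09 ± 0.14) fell while FN1 (1.16 ± 0.061) and VIM (0.41 ± 0.042) rose, these 3 chosen after their values were seen. Of 19 measured epithelial genes, 8 rose and 5 fell (camera adjusted p = 0.88), with CLDN1 (1.49 ± 0.15), EPCAM (0.55 ± 0.074) and LAMB3 (0.28 ± 0.043) up and KRT17 (-0.93 ± 0.040), which has pseudogenes, down. ST14 (-1.09), KRT7 (-0.42) and KRT8 (-0.29) fell too, chosen after their values were seen. The median of the epithelial list was positive at 0.15, but the rotation test fry gave a downward direction that did not pass (fry adjusted p = 0.074). CDH1, chosen after its value was seen, stood near 0.5 CPM in both groups (-0.05 ± 0.31). Among matrix proteases and their inhibitors, 11 of 20 rose and 3 fell, with a median of 0.27 (camera adjusted p = 0.020), a call lost with an estimated correlation (adjusted p = 0.21). CTSB (0.83 ± 0.040), MMP13 (1.38 ± 0.069) and the urokinase receptor PLAUR (0.81 ± 0.043) rose, and the protease inhibitor TIMP3 fell from 37.3 ± 1.94 to 17.6 ± 0.206 CPM (-1.09 ± 0.055). MMP1, chosen after its values were seen, had the largest rise of this list, from 0.114 ± 0.0200 to 1.36 ± 0.118 CPM (3.53 ± 0.33).

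Inflammatory and early-response genes included strong single changes. Of 20 NF-kB and cytokine genes, 4 rose and 8 fell (camera adjusted p = 0.24). The cytokine IL6 fell from 112 ± 3.27 to 53.4 ± 1.17 CPM (-1.07 ± 0.043), the NF-kB inhibitor NFKBIA from 297 ± 14.3 to 138 ± 8.85 CPM (-1.11 ± 0.048) and the chemokine CXCL2 from 54.5 ± 2.77 to 32.4 ± 4.03 CPM (-0.75 ± 0.067), while the adhesion molecule ICAM1 rose from 35.4 ± 1.51 to 67.7 ± 1.62 CPM (0.94 ± 0.048). The other genes that rose, LIF (1.07), CXCL8 (0.66) and CSF1 (0.52), were chosen after their values were seen. Among 28 interferon-stimulated genes, 6 rose and 10 fell (camera adjusted p = 0.16), with ISG15 (-0.92 ± 0.047), OASL (-1.47 ± 0.11) and IFIT3 (-0.66 ± 0.082) down and STAT2 (0.62 ± 0.083) up. Of 18 genes of MHC class I antigen presentation, 10 rose and 4 fell (camera adjusted p = 0.14, and 0.041 with no filter or 0.0035 with DESeq2). The members that led the rise, CANX (1.04 ± 0.041), PDIA3 (0.51 ± 0.038) and CALR (0.57 ± 0.050), are general chaperones of the endoplasmic reticulum, and PSMB8 (-0.46 ± 0.040), an immunoproteasome subunit, fell with PSMB9 (-0.56) and TAPBP (-0.30), which were chosen after their values were seen. Of 26 immediate early genes, 4 rose and 14 fell (camera adjusted p = 0.065). This list passed without Ctrl replicate 2 (adjusted p = 0.039), with no filter (0.019), with the filter of 1 CPM (0.043), with DESeq2 (0.0041), with limma-voom (0.033) and with log2(FPKM + 1) (0.043). NR4A1, an orphan nuclear receptor, fell from 154 ± 1.82 to 50.1 ± 1.09 CPM (-1.62 ± 0.042), with JUNB (-0.87 ± 0.042) and KLF10 (-0.78 ± 0.051), while JUN rose from 253 ± 4.76 to 448 ± 11.2 CPM (0.82 ± 0.039). FOSL1 (0.34), KLF4 (0.33) and MYC (0.23) rose too, chosen after their values were seen.

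Single genes of the splicing machinery changed, and their lists did not pass. Of 38 SR and hnRNP regulators, 12 rose and 11 fell (camera adjusted p = 0.91). The splicing factors RBM5 (0.58 ± 0.039), RBM25 (0.61 ± 0.048) and SRSF11 (0.64 ± 0.052) rose, and PTBP3, a repressor of exon inclusion, fell from 15.4 ± 0.749 to 8.01 ± 0.693 CPM (-0.94 ± 0.077). Of 36 core spliceosome genes, 12 rose and 10 fell over all genes, and 12 and 11 when adjusted over the list alone (camera adjusted p = 0.97). SF3A1 (0.50 ± 0.051) and SF3A2 (0.36 ± 0.046) rose and SNRPD1 (-0.55 ± 0.046) fell. The medians of both lists lay within 0.02 of 0 on the log2 scale. That of the core genes turned positive when libraries were scaled by size only and on both FPKM scales (0.05 in each), and that of the regulators turned negative without Ctrl replicate 2 (-0.006) or MTA1 replicate 1 (-0.009) and after the correction for GC content and length (-0.03).

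In the remaining lists no shift passed camera on the filtered edgeR values of all 6 libraries. Of 24 cholesterol synthesis genes, 12 rose and 8 fell (camera adjusted p = 0.88). DHCR7 (0.56 ± 0.054) rose and IDI1 (-0.84 ± 0.042) fell. The median of the list was positive at 0.12, while fry gave a downward direction that did not pass (fry adjusted p = 0.074). Of 11 luminal prostate genes, 4 rose, with NDRG1 of the hypoxia list among them next to CAMKK2 (0.50 ± 0.065) and ACP3 (0.36 ± 0.076), and 2 fell, with PMEPA1 at -0.36 ± 0.052 (camera adjusted p = 0.44). HOXB13 (-1.33 ± 0.24), a homeobox gene of prostate, fell, chosen after its value was seen. Of 8 neuroendocrine genes, 3 rose, led by the glycolytic enzyme ENO2 (1.66 ± 0.058) and the granin SCG2 (1.2 ± 0.11) ahead of PEG10 (0.16 ± 0.041), and none fell (camera adjusted p = 0.38). The call of PEG10 ended after the correction for GC content and length (adjusted p = 0.081). No list of markers of other cells passed. Of 9 fibroblast markers, THY1 (1.26 ± 0.052) and FAP (2.32 ± 0.27) rose while COL1A1 (-0.94 ± 0.056) and PDGFRB (-0.50, chosen after its value was seen) fell (camera adjusted p = 0.88). The leukocyte list, with 3 measured markers, had a camera adjusted p of 0.69. Of 3 markers of the HEK293 lineage, NEFL fell from 0.828 ± 0.258 to 0.409 ± 0.136 CPM, a call that ended without Ctrl replicate 3 (adjusted p = 0.080) and with DESeq2 (0.055); the list had a camera adjusted p of 0.47. Of 11 structural and nuclear RNAs, a list for RNA quality and library preparation, 4 rose and none fell, led by SNHG1 (1.09 ± 0.049) and TERC (1.43 ± 0.26), with a camera adjusted p of 0.069. This list passed without Ctrl replicate 1 (adjusted p = 0.025) or Ctrl replicate 2 (0.045), with no filter (0.0091) and after the correction for GC content and length (0.022). The share of counts in long non-coding RNAs was lower in the MTA1 group, at 1.52% to 1.56% against 1.68% to 1.72%.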

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

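The protein-coding, GC and length, minimum-fold and reduced NuRD alternatives were chosen after seeing the data, and the others given in this part were fixed before. MTA1 was lower under each alternative, with log2 fold changes from -0.87 with log2(FPKM + 1) to -1.24 without Ctrl replicate 1. The count of genes that passed ran from 7343 with DESeq2, 7247 of them shared with the 8954 and all in the same direction, to 9139 with the replicate block, 8890 of them shared. The replicate numbers did not pair the libraries: over 7428 genes, libraries of the same number correlated at 0.29, -0.09 and 0.07. Those of different numbers ran from -0.32 (Ctrl 1 with MTA1 3) to 0.25 (Ctrl 2 with MTA1 3). A factor that cuts across groups and numbers was not modelled. With a minimum fold of 1.2, 4650 genes passed, 2385 higher and 2265 lower. The genes changed at least 2-fold numbered 600 (277 higher, 323 lower) with the filter of 1 CPM and 620 (276 higher) for protein-coding genes only, where fewer genes were tested. They numbered 529 (286 higher, 243 lower) with log2(FPKM + 0.1) and 149 (83 higher, 66 lower) with log2(FPKM + 1), where the pseudocount shrinks folds of low genes. Both settings also use limma and no TMM scaling, so only the step between them is that of the pseudocount. Lists past the threshold numbered 14 with DESeq2, for which the cause was not tested, 4 with an estimated correlation, and 20 with fry, which does not compare a list with other genes. Without each library in turn, 8145 to 8586 genes passed, 1034 to 1110 changed at least 2-fold, 8 to 10 lists passed, and MTA1 ran from -1.18 to -1.24. Scaling by library size only moved the median of all genes to 0.07, so that 60.1% of the called genes were higher against 50.8%. Of the comparisons for the other genes followed singly, 3977 stayed on their side of the threshold, 17 lost their call and 10 gained one, and none reversed a called direction. For the lists, 528 stayed, 5 lost the call, each with an estimated correlation, and 32 gained it. That correlation was 0.63 for the mitochondrial list. It was only -0.028 for the NuRD, 0.0055 for the heat shock and 0.013 for the matrix protease list, near or below the preset 0.01. High correlation among members therefore does not account for these last 3 losses. The hypoxia list, at -0.026, also moved from a camera p of 8.0e-10 to 0.0025 with this setting. A call lost with an estimated correlation therefore need not come from correlated members. Mesenchymal genes (adjusted p = 0.00034), luminal prostate genes (0.038) and neuroendocrine genes (0.041) passed with DESeq2.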

Other observations

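Glycolytic, collagen and BMP-target genes were among 8 lists written after the first results were seen, each of which passed camera against the other genes, and their example genes were chosen after their values were seen. Some members, such as ID2, COL5A3 and SLC2A1, had been seen to change before their list was written, so each list was tested again without members that a fixed list holds or the naming rule takes. Of 24 glycolytic genes, 20 rose and 1 fell (20 and 2 when adjusted over the list alone), with a median log2 fold change of 0.48 (adjusted p = 2.6e-06, and 0.015 with an estimated correlation). Without 8 such members the adjusted p was 0.0021, lost at adjusted p = 0.068 with an estimated correlation. They share members such as HK2 (1.29 ± 0.057), PGK1 (0.66 ± 0.038) and LDHA (0.15 ± 0.040) with the hypoxia list, and PDK3 (-0.31 ± 0.066) fell while GAPDH stood at -0.06, passing as lower without MTA1 replicate 3 (adjusted p = 0.021). Of 26 collagens and collagen-modifying enzymes, 21 rose and 2 fell (23 and 2 when adjusted over the list alone), with a median of 0.65 (adjusted p = 3.9e-08, and 0.034 with an estimated correlation), and without 5 such members 1.1e-07 (adjusted p = 0.042 with an estimated correlation). SERPINH1, a collagen chaperone, rose from 115 ± 2.13 to 285 ± 0.886 CPM (1.30 ± 0.039), with COL6A1 (1.05 ± 0.046) and LOXL2 (1.58 ± 0.064), while COL1A1 (-0.94 ± 0.056) and P4HA3 (-0.61 ± 0.047) fell. Of 12 ID genes and BMP feedback targets, 9 fell and 1 rose, with a median of -0.98 (adjusted p = 0.00010, lost at adjusted p = 0.065 with an estimated correlation), and without ID2 it was -0.73 (adjusted p = 0.00046, lost at adjusted p = 0.091 with an estimated correlation). ID1 fell from 178 ± 5.85 to 73.4 ± 4.88 CPM (-1.28 ± 0.048), with ID3 (-1.49 ± 0.060) and SMAD6 (-1.23 ± 0.077), and the BMP antagonist GREM1 rose (1.18 ± 0.13).

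Nuclear genes for oxidative phosphorylation fell where the mitochondrial transcripts rose. Of 69 such genes, 51 fell and 5 rose, with a median of -0.31 (adjusted p = 3.9e-08, and 0.015 with an estimated correlation). UQCRB (-0.95 ± 0.046), COX6C (-0.84 ± 0.042) and NDUFB1 (-0.89 ± 0.038) fell, and UQCRC1 (0.31 ± 0.039), SDHA (0.23 ± 0.041) and NDUFB5 (0.19 ± 0.049) were among those that rose. Lists matched to them on coding length and expression had a median of -0.15 (95% between -0.23 and -0.06), and the median of the genes themselves lay below that range (permutation p = 4e-04), while its interval, -0.36 to -0.22, reached into it. After the fit of the trend with GC content and length their median was -0.21 (interval -0.32 to -0.16). Of 21 NRF2 targets, 15 fell and 6 rose, with a median of -0.32 (adjusted p = 0.0046, lost at adjusted p = 0.15 with an estimated correlation, and without 2 such members 0.0034, lost at adjusted p = 0.15 with an estimated correlation). AKR1C1 (-1.16 ± 0.039), HMOX1 (-1.12 ± 0.055) and NQO1 (-0.61 ± 0.039) fell and the cystine transporter SLC7A11 (0.63 ± 0.059) rose. Of 20 cytosolic aminoacyl-tRNA synthetases, 16 rose, such as MARS1 (0.75 ± 0.039) and EPRS1 (0.75 ± 0.039), and 1 fell (16 and 2 when adjusted over the list alone), with a median of 0.34 (adjusted p = 0.00010, lost at adjusted p = 0.10 with an estimated correlation). Of 31 proteasome subunits, 16 rose, such as PSMD3 (0.52 ± 0.045) and PSMD2 (0.43 ± 0.042), and 6 fell, such as PSMA3 (-0.22 ± 0.041), a call that ended after the correction for GC content and length (adjusted p = 0.26); the list had a median of 0.17 (adjusted p = 0.030, lost at adjusted p = 0.091 with an estimated correlation).

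Of the tests that follow, the count for a culture difference was chosen only after the result was seen; the coding-length test was added after a first test on transcript length, with its own result not yet known. The rise of the hypoxia and unfolded protein response lists (medians 0.66 and 0.55) was weighed first. A trend with GC content and length is argued against: after a fit of that trend the medians were 0.605 (95% bootstrap interval 0.505 to 0.969) and 0.569 (0.393 to 0.799). Counts taken by a few abundant genes are argued against as well, since the smallest hypoxia median over the scaling alternatives was 0.657. What stays open is a difference between the cultures in density, medium or oxygen at harvest, next to lasting differences between stable lines and an effect of less MTA1. None of these had a direction set beforehand for the hypoxia genes, of which 21 of 23 rose. A difference in RNA quality or library preparation was not weighed for these lists, and further causes may be open. The causes cannot be told apart, because the labels describe no separate cultures of a line.

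The fall of 49 of 50 ribosomal protein genes (median -0.44) was weighed next. After the fit of the trend with GC content and length, the median was -0.392 (interval -0.436 to -0.299). With library size only, the scaling that left least of the fall, it was -0.369. Each left most of the fall in place. Reads shared with pseudogenes stay open. The sums of 48 genes with 329 pseudogenes had a median of -0.437 (interval -0.467 to -0.342). The pseudogenes held a median of 0.13% of those reads, so the sums could hardly differ from the genes alone. How reads that match both were counted is not given. Across 12599 protein-coding genes, which are not independent replicates, log2 fold change rose with coding length (Spearman 0.225), and of 10000 lists matched on coding length and expression 95% had medians between -0.304 and -0.0763. The ribosomal protein median and its interval (-0.468 to -0.368) lay below that range (permutation p over gene lists = 2e-04, the smallest these lists can give). Part of the fall may be shared with short, abundant messages. Whether all of it is cannot be told. The lists drew on 402 genes nearest in rank, whose CPM was not compared with that of the ribosomal protein genes. The transcript length used in the first fit is that of the longest annotated transcript, which overstates the messages of genes such as RPL13.

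A hypothesis was that other messages with a 5-prime terminal oligopyrimidine start (TOP), a motif of translation genes, fell along with ribosomal protein genes. The list of 22 was written before its test, though the counts of HNRNPA1 and NPM1 had been seen. Of its members 20 fell, among them NAP1L1 (-0.96 ± 0.039), TPT1 (-0.73 ± 0.041) and EIF4B (-0.66 ± 0.038), which have pseudogenes, and the median was -0.406 (adjusted p = 3.0e-07, and 0.015 with an estimated correlation). Without HNRNPA1 and NPM1 the adjusted p was 1.4e-07 (adjusted p = 0.022 with an estimated correlation). Lists matched on expression lay between -0.239 and 0.141 (permutation p = 0.001), and lists matched on coding length as well between -0.209 and 0.163. NPM1 rose (0.11 ± 0.043), a call that ended without Ctrl replicate 2 (adjusted p = 0.13), Ctrl replicate 3 (0.061) or MTA1 replicate 1 (0.085). PABPC1 stood at 0.07 and passed as higher with library size only (0.14), log2(FPKM + 0.1) (0.14) and log2(FPKM + 1) (0.13). A shared control of TOP messages is a candidate explanation, found and tested on the same data.

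The number of genes that passed (8954) was weighed last. Copy number differences of whole chromosomes are argued against: the chromosome farthest from the median of all genes was 14, at -0.0772 (interval -0.118 to -0.0283), short of the 0.2 set beforehand for a gain or loss, although the medians of the 23 chromosomes varied more than in shuffled gene orders (permutation p = 0.01). For blocks of 25 neighbouring genes the largest shift was -0.542 on chromosome 21, beyond the 95th percentile of the largest in 1000 shuffles (0.501) but not beyond the largest (0.659), so a block there cannot be told apart from a chance run, and it held 1 of 14692 windows. A trend with GC content and length is argued against by the 8805 genes called after its correction, and very small changes account for part of the calls, since 4650 (51.9% of the number, and 51.5% to 52.4% without each library in turn) passed with a minimum fold of 1.2. An effect of less MTA1 and lasting differences between stable lines both remain untested. These need not be the only open causes. The labels name lentivirus and the screening of stable clones, but not the number of hairpins or clones. They also do not say whether the lines were infected and selected separately.

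The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split was the 1 with the highest counts in each case: 8954 genes in edgeR against at most 0 in the others, 954 genes changed at least 2-fold against at most 0, and 8 lists against at most 6. Each of the other 9 splits called 3 to 6 lists at the preset correlation while calling no gene, the hypoxia and ribosomal protein lists in each, so a preset call did not require genes past the threshold. These splits set 2 libraries of a group and 1 of the other against the reverse, which keeps part of the difference between the groups. They also put libraries of both groups on each side, so the group difference adds to the spread within a side. The 0 genes called in them could therefore be foreseen, and no conclusion is drawn from that count. With an estimated correlation, a test chosen after the data were seen, the real split called 4 lists and the others 0. No conclusion is drawn from that contrast either.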
